A study of Mus musculus with 4 samples.

How the data were processed

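RNA was measured in dorsal cortex taken directly from mouse embryos at E18.5 (embryonic day), with 4 arrays in 2 groups. The 2 control embryos carry 1 floxed and 1 wild-type copy of Mek1 and lack Mek2, per the labels. The 2 mutant embryos carry only floxed copies of Mek1, lack Mek2, and carry NestinCre, a transgene that expresses Cre recombinase in neural progenitors and their descendants. The series' design text calls the controls wild type, whereas the genotype labels give them as null for Mek2. The comparison is therefore described here as loss of Mek1 on a background without Mek2. The labels name NestinCre for the mutants only, so an effect of the transgene itself cannot be told apart from the loss of Mek1. Gene symbols for Mek1 and Mek2 are Map2k1 and Map2k2. Nothing in the labels gives a litter, a scan date or a batch, or says that the arrays of a group come from separate embryos. The limma p-values therefore measure the spread between these samples.

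Per the labels' protocols, total RNA (200 ng per array) was extracted with Trizol, purified on columns, and labelled with biotin by a whole-transcript sense target protocol for a single-colour array. The deposited table holds log2 expression values made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the probes over the arrays and summarises them into 1 value per feature. The version of RMA, the software that ran it, the genome build and any filter are not given in the sources used here, and the log base was read from the range of the values. Because RMA brings all arrays to a similar distribution, a change shared by most transcripts cannot be seen in these values, and folds of dim genes are compressed towards 0. No scanner intensities were used here, so no flag for signal over background was at hand, and the number of arrays limits the precision.

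The table has 35557 features on each array, and the medians of the 4 arrays lay between 7.11 and 7.13. Names came from the platform annotation, in which 21789 features have 1 gene symbol, 1621 have several, and 12147 features of the table are not listed. Symbols were looked up by Entrez identifier in the mouse RefSeq gene table (assembly GRCm38.p6), which matched 21698 of the 21789 and left 91 with the symbol of the platform annotation. Features without a single symbol were left out, and for the 999 genes with several features the brightest feature was kept, which left 19938 genes. Genes whose mean over the 4 arrays lay under the 30th percentile of these genes (log2 6.16) were left out, and 13956 genes were tested. No coordinates are given, because the build behind the array's annotation is not given in the sources used here.

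The mutant and control groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, no covariate). P-values were adjusted with the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Differences are mutant minus control on the log2 scale with their moderated standard error, and values per group are mean ± SD with n = 2. The fit had 2 residual degrees of freedom, to which the shared prior added 3.31. A set of 32 gene lists was fixed from textbook knowledge before the data were examined, as were the tests, the filter, the rule for named genes and the alternatives, apart from those said to have been added. In all, 31 lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera sets the genes of a list against the other genes. At this preset the genes count as nearly independent, so its p-values depend on gene number and do not measure the spread between samples alone. Correlations estimated from these arrays ran from -0.13 for the myelin list to 0.76 for the intermediate progenitor list. Camera with an estimated correlation and fry, a rotation test of a list on its own, were alternatives. The list of sex-linked genes served as a check of the embryos. Of 604 genes on the lists, 485 were tested, and some genes stand on several lists.

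The named genes are Map2k1 and Map2k2, the 12 called genes with the largest difference in each direction whose groups did not overlap, and members of the lists. Where fewer than 12 genes passed in a direction, the genes with the smallest p that differed by at least 0.5 without overlap filled the group up to 6, and are given as not passing. For a list whose shift passed, the 4 members with the smallest p in its direction are named, and for other lists 2. Predicted genes without an assigned name and olfactory or vomeronasal receptors were skipped. Genes named outside this rule are said to have been chosen after their values were seen.

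The fit was tested on simulated data with the means of the same 13956 genes, in which 200 genes were changed in each of 20 runs. Each gene's spread was drawn from the fitted prior, and genes varied independently. Deviations that many genes of an array share are not covered, so the rates that follow hold for independent genes only. It recovered 61.3% of genes changed by 0.5 on the log2 scale, 95.7% of those changed by 1 and 99.6% of those changed by 2, and 5.32% of the calls were false. The alternatives were no filter, a stricter filter (50th percentile), an intensity trend with and without robust eBayes, further quantile normalization or median centring, the mean of a gene's features, the replicate number as a block, each array left out in turn, every feature tested, each list without the genes it shares with others, and an adjusted p under 0.1. Embryo sex as a covariate was added after the data were examined, because the sex-linked genes showed that both sexes were present.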

Results

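Dorsal cortex of mouse embryos at E18.5 (embryonic day) was profiled on 4 single-colour whole-transcript arrays. The series compared 2 embryos in which Mek1 was deleted by NestinCre on a Mek2-null background with 2 controls that also lacked Mek2 but kept a wild-type copy of Mek1, per the labels. MEK1 and MEK2 are the kinases that phosphorylate ERK1 and ERK2. At this age the cortex is passing from making neurons to making glia. The comparison addresses which transcripts of the late embryonic cortex differ when Mek1 is lost as well as Mek2. NestinCre, named in the labels for the mutants only, goes together with that loss. Values are log2 expression as deposited, normalized by the authors with RMA.

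The arrays were close to each other. Over the 13956 genes tested, the 2 controls differed by a root mean square of 0.149 on the log2 scale and the 2 mutants by 0.191. The differences between a control and a mutant lay between 0.178 and 0.230. Mutant 1 stood further from the controls than mutant 2, with a root mean square distance from the control mean of 0.213 against 0.169. Xist, the RNA of the inactive X chromosome, was at 11.9 on the control 1 and mutant 2 arrays and at 5.35 and 4.81 on control 2 and mutant 1. The Y-linked genes Kdm5d, Eif2s3y and Uty showed the opposite pattern, so each group held 1 female and 1 male sample, which come from different embryos.

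The targeted gene was measured first. Map2k1 was at 8.80 ± 0.06 (SD, n = 2) in controls and 8.61 ± 0.16 (SD, n = 2) in mutants, a difference of -0.19 ± 0.09 (SE) that did not pass the test (limma, adjusted p = 0.469). Its 4 values were 8.76 and 8.84 in controls and 8.50 and 8.73 in mutants. The feature summarises probes along the whole transcript, and which of them lie in a deleted part is not given in the sources used here, so it neither shows nor excludes the deletion. Map2k2, null in both groups per the labels, was at 8.52 ± 0.07 and 8.61 ± 0.05 (SD, n = 2 each), with an adjusted p of 0.657 in limma. Its signal does not show the absence of Mek2 in either group, and the same limit on probes holds for it.

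Genes of the glial lineages, of radial glia and of the cell cycle were among those that were lower in the mutants. In the limma fit 141 genes were lower in the mutants and 2 were higher at an adjusted p under 0.05. Pdgfra, the PDGF receptor that marks oligodendrocyte precursors, fell 6.23-fold, from 8.79 ± 0.26 to 6.15 ± 0.20 (SD, n = 2 each; adjusted p = 0.00934). Its mutant mean lies under the mean under which genes were left out as dim (6.16), as do those of Gpr17 (5.84), Fcrls (6.07), Olig2 (6.01) and Neurod4 and the control mean of Anxa1 (5.73), so the size of these differences depends on the background, for which no detection limit was at hand. Tnc, an extracellular matrix protein of radial glia and astrocytes, fell 4.62-fold (adjusted p = 0.0135), and Olig1, an oligodendrocyte lineage transcription factor, fell 4.46-fold (adjusted p = 0.0251). The glial genes Acsbg1, a fatty acyl-CoA synthetase, Fabp7, a fatty acid binding protein, Aldoc, a glycolytic aldolase, and Slc1a3, the glutamate transporter GLAST, fell between 2.88-fold and 3.25-fold (adjusted p = 0.00538 for each). The rest of the 12 largest decreases among called genes were in Slc15a2, a peptide transporter (2.87-fold), Bcan, the proteoglycan brevican (2.79-fold), Aldh1l1, a folate enzyme used as an astrocyte marker (2.72-fold), Etv5, an ETS transcription factor downstream of ERK (2.62-fold), and Mfge8, a secreted glycoprotein (2.61-fold).

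In the other direction only Rhob, a small GTPase, and Bbc3, the pro-apoptotic protein PUMA, passed the test in the limma fit. Rhob rose 1.49-fold, from 10.15 ± 0.05 to 10.73 ± 0.04 (SD, n = 2 each; adjusted p = 0.0278), and Bbc3 rose 1.41-fold (adjusted p = 0.0428). Neither was called without control 1, without control 2 or when dim genes were kept. Among the other genes higher by at least 0.5 with no overlap between the groups, the smallest p belonged to Cnmd (difference 0.80, adjusted p = 0.0519), Kcnip4 (0.53, adjusted p = 0.0615), Prkch (0.54, adjusted p = 0.0790) and Sulf1 (0.70, adjusted p = 0.0862), which did not pass in limma. By size alone, 34 genes were lower and 1 was higher by at least 1 on the log2 scale with no overlap between the groups, and 28 of these were among those called. The 1 higher gene was Anxa1, annexin A1, named after its value was seen (1.03, adjusted p = 0.287 in limma).

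**Figure D1:**
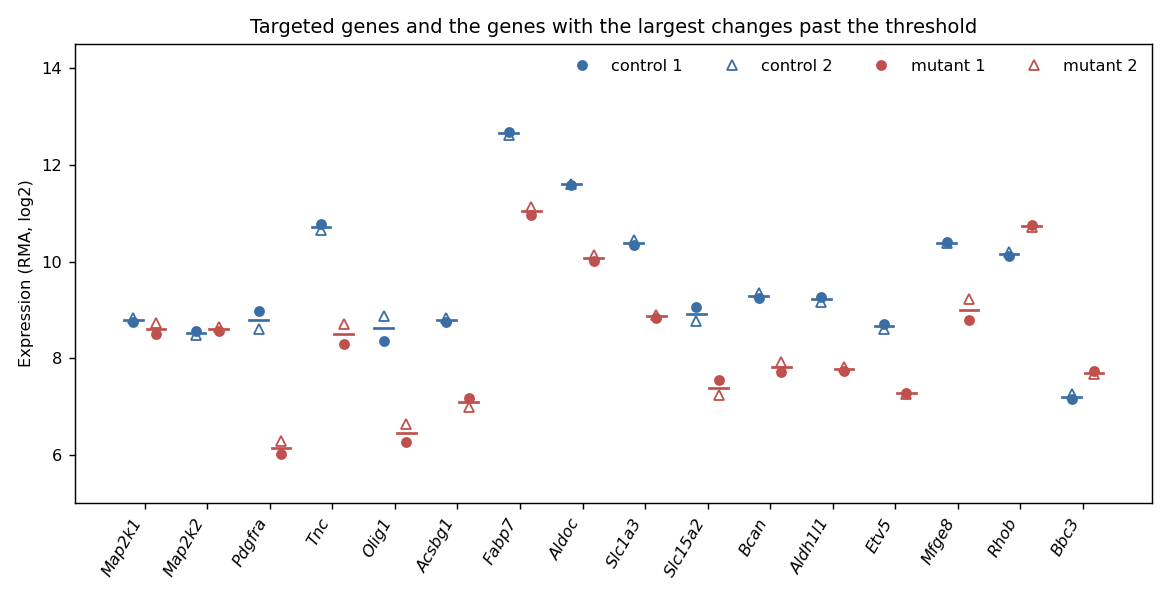
Expression (RMA, log2, y axis) of Map2k1, Map2k2, the 12 called genes with the largest decreases and the 2 genes that rose, on each of the 4 arrays (points; filled for replicate 1, open for replicate 2), with group means as lines. Pdgfra lies at 8.79 in controls and 6.15 in mutants, and Rhob at 10.15 and 10.73.

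At an unadjusted p under 0.05, 1073 genes were lower and 799 higher, where chance alone gives 697.8 in all. That imbalance was 948 against 934 with each array centred on its median, and 1008 against 1059 without mutant 1. The groups did not overlap in 44.3% of the genes tested, where chance gives 33.3%. The 4 arrays can be split into pairs in only 3 ways, and 33.3% is the average over these splits. Deviations that many genes of an array share can raise the share of 1 split, and can move the number of genes at an unadjusted p under 0.05. Neither excess is therefore a test of genotype. The number of calls in limma depended on each array: it was 9 without control 1, 9 without control 2, 262 without mutant 1 and 881 without mutant 2. With embryo sex as a covariate, chosen after seeing the data, 17 genes were called. Each group held 1 female and 1 male sample, so the differences themselves stayed the same. The covariate took up part of the 2 residual degrees of freedom. Leaving out a control likewise left fewer of them, with the spread taken from the mutant pair alone. Acsbg1, Aldh1l1, Aldoc, Cybrd1, Etv5, Fabp7, Pdgfra and Slc1a3, 8 genes, were called under each of the 13 other fits of the named genes, and none was called when every feature of the table was tested.

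Astrocyte lineage genes fell as a group. Of 25 measured, 7 fell, none rose, and 18 did not pass; adjusted over the list alone, 14 fell. The median difference was -0.53, and the list was shifted down in camera (adjusted p = 8.78e-17; adjusted p = 0.44 with an estimated correlation). Slc1a3 went from 10.39 ± 0.06 to 8.87 ± 0.04, Aldoc from 11.60 ± 0.01 to 10.07 ± 0.08, Fabp7 from 12.65 ± 0.04 to 11.05 ± 0.11 and Aldh1l1 from 9.22 ± 0.07 to 7.77 ± 0.06 (SD, n = 2 each). Gfap, an intermediate filament of mature astrocytes named here after its value was seen, was dim in both groups, at 7.01 ± 0.15 and 7.05 ± 0.21 (SD, n = 2 each).

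Genes of oligodendrocyte precursors fell by the same test. Of 16 measured, 4 fell and none rose (9 fell adjusted over the list alone), and the median difference was -0.38 (camera adjusted p = 1.57e-07; adjusted p = 0.38 with an estimated correlation). Beside Pdgfra and Olig1 these were Gpr17, a receptor of committed precursors (1.92-fold, adjusted p = 0.0331 in limma), and Gng12, a G protein subunit (1.43-fold, adjusted p = 0.0409 in limma). Without control 1 the members that fell numbered 2, and without control 2 there was 1. The 7 myelin genes measured, of 12 on the list, showed no shift past the threshold (median difference 0.01, adjusted p = 0.60 in camera). Adjusted over the list alone, 2 of them fell. Their median level in controls was 6.66, close to the level of the filter on dim genes (6.16). Differences of dim genes are compressed towards 0, so a fall of the myelin list could be hidden. Ugt8a, an enzyme of myelin lipid synthesis, differed by -0.51 (adjusted p = 0.0643) and Cnp by -0.37 (adjusted p = 0.148), neither past the threshold in limma.

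Radial glia and neural stem cell genes fell as a group too, and 4 of them stand on another list. Of 23 measured, 8 fell and none rose (18 fell adjusted over the list alone), with a median difference of -0.47 (camera adjusted p = 1.43e-20; adjusted p = 0.44 with an estimated correlation). Slc1a3, Fabp7 and Tnc stand on the astrocyte list too; Hopx, a homeodomain protein of radial glia, fell 1.70-fold (adjusted p = 0.0254 in limma). Without control 1 and without control 2, 2 members were called in each case.

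Cell cycle genes were lower without exception. All 30 measured had a lower mean in the mutants, 12 fell past the threshold over all genes, and 29 fell adjusted over the list alone. The median difference was -0.56 (camera adjusted p = 2.41e-31; adjusted p = 0.38 with an estimated correlation). Mcm3, a subunit of the replicative helicase, fell 2.00-fold, Mki67, the Ki-67 proliferation antigen, 2.05-fold, Bub1, a mitotic checkpoint kinase, 2.10-fold, and Top2a, topoisomerase II alpha, 1.93-fold (limma adjusted p between 0.0185 and 0.0251). A dimmer feature for Top2a differed by -0.21. No member was called without control 1, without control 2 or when dim genes were kept.

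ERK pathway feedback and target genes fell as a group. Of 22 feedback and target genes, 5 fell and none rose in limma; adjusted over the list alone, 15 fell and 1 rose. The median difference was -0.35 (camera adjusted p = 9.57e-13; adjusted p = 0.44 with an estimated correlation). Etv5 went from 8.66 ± 0.07 to 7.27 ± 0.01 (SD, n = 2 each), and the other feature for Etv5 differed by -1.55. Spred3 and Spred1, inhibitors of the RAS to ERK cascade, fell 1.94-fold and 1.42-fold, and the ETS factor Etv4 fell 1.65-fold (limma adjusted p between 0.0185 and 0.0314). Only Etv5 remained called without control 1 or without control 2.

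Of 15 activity-regulated immediate early genes, none passed in limma over all genes or over the list alone, and the median difference was -0.00 (camera adjusted p = 0.97). Their differences ran from -0.28 for Nptx2, a synaptic pentraxin (adjusted p = 0.188), to 0.23 for Arc, a synaptic plasticity protein (adjusted p = 0.187). The median of these genes in controls was 7.03, against 8.56 for the feedback and target genes. The mean differences of the lists, -0.39 and -0.01, differed by a permutation test that moved genes between them (two-sided p = 0.00048, 100000 resamples), in which genes are not independent replicates.

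**Figure D2:**
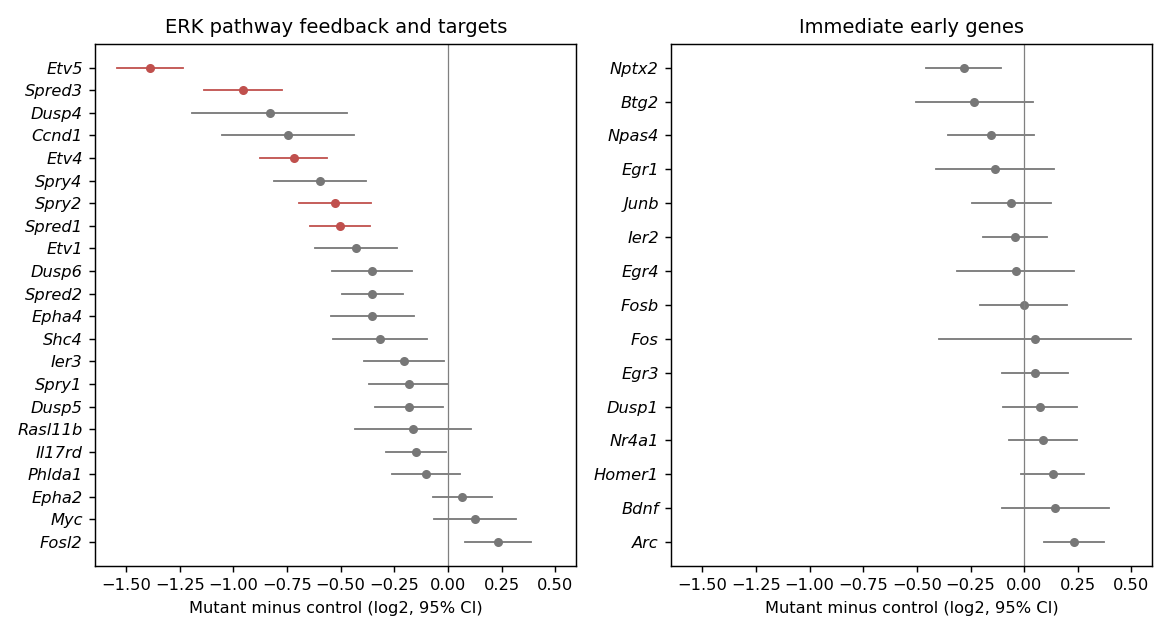
Difference between mutants and controls (log2, x axis) for 22 ERK pathway feedback and target genes and 15 immediate early genes, as points with the 95% confidence interval of the limma fit; red marks an adjusted p under 0.05. Etv5 lies lowest at -1.39, and no immediate early gene lies outside -0.28 to 0.23.

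The list of gliogenic regulators and cytokine pathway genes gave a mixed picture. Of 17 measured, 2 fell and none rose (4 fell adjusted over the list alone): Etv5 and Sox9, a transcription factor of gliogenesis (1.62-fold, adjusted p = 0.0320 in limma), of which Etv5 alone was called without control 1 or without control 2. Olig2, the partner of Olig1, differed by -1.85 (adjusted p = 0.0567) and Sox8 by -0.59 (adjusted p = 0.0699), neither past the threshold in limma. The median (0.00) and the mean (-0.30) differ in sign, and the camera call (adjusted p = 0.029) was lost with an estimated correlation (adjusted p = 0.45). It was also lost without the 4 genes shared with other lists (adjusted p = 0.85), under the stricter filter (adjusted p = 0.102) and after further quantile normalization (adjusted p = 0.060). Nfia, Nfib and Nfix, nuclear factors of gliogenesis named after their values were seen, differed by 0.00 ± 0.06, -0.04 ± 0.05 and 0.10 ± 0.05 (SE).

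Notch pathway genes shifted down. Of 14 measured, 2 fell and none rose (6 fell adjusted over the list alone), with a median difference of -0.31 (camera adjusted p = 1.86e-06; adjusted p = 0.45 with an estimated correlation). Nrarp, a feedback inhibitor of Notch, fell 1.59-fold (adjusted p = 0.0338 in limma), and the receptor Notch1 fell by 0.58 on the log2 scale (adjusted p = 0.0456). Neither was called without control 1, without control 2 or when dim genes were kept. Notch2 differed by -0.75 (adjusted p = 0.0647) and Hes1, a Notch effector, by -0.40 (adjusted p = 0.126), neither past the threshold in limma. The BMP list did not pass in camera (median -0.14, adjusted p = 0.094), with Smad7 at 0.26 and Bmpr1a at -0.23 (adjusted p = 0.196 for both in limma); 3 members fell and 1 rose adjusted over the list alone. It passed without control 2 (adjusted p = 0.032) and without mutant 1 (adjusted p = 0.0076). The Wnt list did not pass in camera either (median -0.03, adjusted p = 0.24), and in it Sfrp1, a secreted Wnt antagonist, differed by -0.58 (adjusted p = 0.0546) and Znrf3 by -0.35 (adjusted p = 0.0797) in limma; 2 members fell and 1 rose adjusted over the list alone.

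In the MAPK cascade the adaptor Shc3 fell 2.35-fold (adjusted p = 0.00934) and Map3k1 differed by -0.58 (adjusted p = 0.0517) in limma. The list of 25 components had a median of 0.03 (camera adjusted p = 0.85) with 1 member called, lower; adjusted over the list alone, 2 fell and 1 rose. Shc3 was not called without control 1 or without control 2. Among 27 growth factor receptors and ligands, Pdgfra and the receptor Egfr (2.33-fold, adjusted p = 0.0278 in limma) fell, none rose, and the list as a whole did not shift past the threshold (median -0.00, camera adjusted p = 0.44); adjusted over the list alone, 3 fell. Egfr was not called without control 1 or when dim genes were kept.

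Neuronal lists had smaller median differences than the astrocyte, radial glia and cell cycle lists, though some of them passed in camera. Intermediate progenitor genes shifted down in camera (14 measured, median -0.20, adjusted p = 7.75e-04; adjusted p = 0.65 with an estimated correlation). The list lay at -0.27 in mutant 1 and at -0.09 in mutant 2. The only member called was Slco1c1 (2.13-fold, adjusted p = 0.0265 in limma), a thyroid hormone transporter that is also known from brain endothelium and glia; it was not called without control 1, without control 2 or when dim genes were kept. Insm1 (-0.25, adjusted p = 0.210), Neurod4 (-0.64, adjusted p = 0.334) and Mfng (-0.19, adjusted p = 0.304) did not pass in limma. Deep-layer projection neuron genes shifted up (19 measured, none called, median 0.14, camera adjusted p = 0.022; adjusted p = 0.44 with an estimated correlation), and the call was lost without mutant 1 (median 0.08, adjusted p = 0.091). Adjusted over the list alone, 2 members rose and 1 fell. The members with the smallest p in that direction were Hs3st4 (0.45, adjusted p = 0.0648), Nfe2l3 (0.38, adjusted p = 0.136), S100a10 (0.86, adjusted p = 0.209) and Sox5 (0.41, adjusted p = 0.239) in limma. Etv1, named after its value was seen, went the other way (-0.43, adjusted p = 0.0943).

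Upper-layer genes (17 measured, median 0.01, camera adjusted p = 0.57), GABAergic interneuron genes (19 measured, median 0.00, adjusted p = 0.91) and genes of neuronal maturation and synapses (23 measured, median 0.02, adjusted p = 0.30) showed no shift past the threshold, and none of their members was called over all genes or adjusted over the list alone. The interneuron list passed without mutant 2 (median -0.09, adjusted p = 0.046). Inhba (0.56, adjusted p = 0.236), Mdga1 (0.18, adjusted p = 0.277), Npy (0.30, adjusted p = 0.324), Dlx1 (-0.16, adjusted p = 0.461), Camk2b (0.16, adjusted p = 0.355) and Tubb3 (0.17, adjusted p = 0.382) had the smallest p of these lists in limma. Cajal-Retzius cell genes were shifted down (9 measured, none called, median -0.17, camera adjusted p = 0.032; adjusted p = 0.65 with an estimated correlation), and the call was lost without control 1 (median -0.15, adjusted p = 0.083) and without mutant 1 (median 0.05, adjusted p = 0.92). Cxcr4 (-0.17, adjusted p = 0.308), Ndnf (-0.27, adjusted p = 0.334), Reln (-0.17, adjusted p = 0.489) and Trp73 (-0.10, adjusted p = 0.606) led that list in limma.

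**Figure D3:**
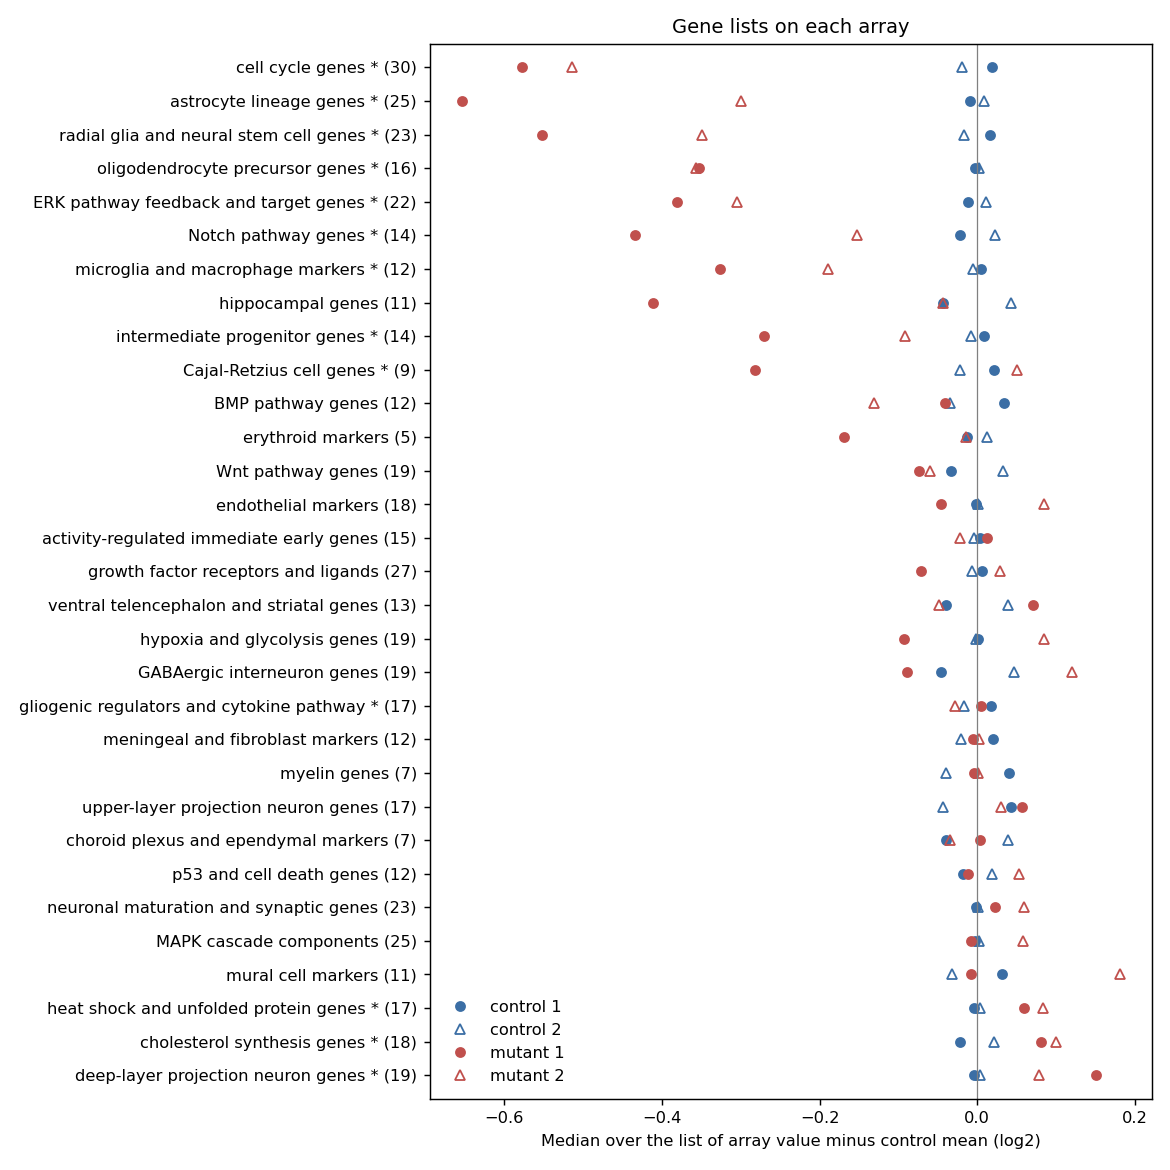
Median over the genes of each list of the array's value minus the control mean (log2, x axis) for the 31 lists tested, on each of the 4 arrays; the number of genes tested stands in brackets and a star marks a camera adjusted p under 0.05. The cell cycle list lies at -0.58 and -0.51 in the mutants, and the hippocampal list at -0.41 in mutant 1 and -0.04 in mutant 2.

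Markers of other cells and regions were measured as a check of the dissection. Microglia and macrophage markers were lower in the mutants (12 measured, 1 called, median -0.27, camera adjusted p = 6.37e-06; adjusted p = 0.38 with an estimated correlation), and adjusted over the list alone 7 fell. Fcrls, a microglial Fc receptor-like protein, fell 1.58-fold (adjusted p = 0.0254), though not past the threshold without control 1, without control 2 or when dim genes were kept, while Laptm5 (-0.53, adjusted p = 0.122), C1qb (-0.36, adjusted p = 0.149) and Cx3cr1 (-0.28, adjusted p = 0.206) did not pass in limma. No shift past the threshold was seen in camera for endothelial (median -0.00, adjusted p = 0.87), mural (0.04, adjusted p = 0.16), meningeal (0.00, adjusted p = 0.97), erythroid (-0.08, adjusted p = 0.088) or choroid plexus and ependymal markers (0.01, adjusted p = 0.96). The smallest p values among them belonged to Mfsd2a (-0.36) and Eng (-0.18), Higd1b (0.18) and Ndufa4l2 (0.19), Col3a1 (0.14) and Col6a3 (0.14), Alas2 (-0.23) and Slc25a37 (-0.10), and Foxj1 (0.15) and Folr1 (-0.12), none of them called. The erythroid list passed without mutant 2 (median -0.17, adjusted p = 0.026), and the mural list passed, upwards, without mutant 1 (median 0.18, adjusted p = 0.048) and without the genes shared with other lists (adjusted p = 0.034).

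Ventral telencephalic and striatal genes (median -0.00, camera adjusted p = 0.82) did not shift past the threshold (1 member rose adjusted over the list alone), with Ppp1r1b at 0.52 (adjusted p = 0.122) and Zic1 at -0.54 (adjusted p = 0.191) in limma. Hippocampal genes had a median of -0.25 (camera adjusted p = 0.068) with Lef1 at -0.31 and Zbtb20 at -0.40. The list passed without mutant 2 (median -0.41, adjusted p = 0.0019) and without control 1 (median -0.29, adjusted p = 0.025). In mutant 1, where it lay at -0.41, the astrocyte list lay at -0.65 and the radial glia list at -0.55, against -0.04, -0.30 and -0.35 in mutant 2.

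Of the stress and metabolic lists, cholesterol synthesis genes shifted up by a small amount (18 measured, 16 with a higher mean, none called, median 0.11, camera adjusted p = 7.75e-04; adjusted p = 0.45 with an estimated correlation). Adjusted over the list alone 1 member rose. Hsd17b7 (0.39, adjusted p = 0.0548), Mvd (0.23, adjusted p = 0.196), Fdft1 (0.17, adjusted p = 0.308) and Cyp51 (0.15, adjusted p = 0.323), enzymes of sterol synthesis, led it in limma. Heat shock and unfolded protein genes shifted up by 0.07 (17 measured, none called, camera adjusted p = 0.040; adjusted p = 0.62 with an estimated correlation), with Ddit3 at 0.19, Dnajb1 at 0.20, Asns at 0.16 and Hspa1a at 0.23. That call was lost without control 1, without mutant 1 and without mutant 2 (adjusted p = 0.090, 0.054 and 0.107), and with the mean of a gene's features (adjusted p = 0.087). The p53 and cell death list did not shift (median 0.02, camera adjusted p = 0.56; 2 rose and 1 fell adjusted over the list alone). Bbc3 rose, and Bcl2l11, a related pro-apoptotic gene, differed by -0.34 (adjusted p = 0.0791 in limma). Hypoxia and glycolysis genes did not shift (median 0.00, camera adjusted p = 0.69), with P4ha1 at -0.27 and Egln3 at -0.28.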

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

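Of 13768 features without a single gene name, which the comparisons of genes did not use, 48 were higher in both mutants by at least 1 on the log2 scale and 38 were lower. None passed limma's test over every feature, in which the lowest adjusted p was 0.178, and 1487 features were lower and 1516 higher at an unadjusted p under 0.05.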

How the results depend on the processing

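The 143 genes called, where present, kept their direction under each of the 13 other fits in limma, but the number of calls depended on the settings. For most fits the direction was fixed in advance. The groups did not overlap in any of the 143, so leaving out 1 array could not turn a direction. The filters, the trends, the block and the sex covariate left the difference itself unchanged. A lack of reversals, here and below, is therefore weak evidence. The 141 genes called lower and 2 genes called higher became 15 and 0 with no filter on dim genes, 217 and 21 with an intensity trend, 268 and 33 with a robust trend, 290 and 29 at an adjusted p under 0.1, and 0 and 0 with every feature tested (1487 and 1516 at an unadjusted p under 0.05). In the last case the shared prior fell to 2.10 degrees of freedom. With embryo sex as a covariate, added after seeing the data, they became 17 and 0. The stricter filter gave 130 lower genes, of which 86 were the same, and 11 higher genes; centring gave 4 higher genes. Leaving out 1 array gave 9 to 731 lower and 0 to 150 higher genes, with 9 and 0 without either control and with the most calls without mutant 2, where the lone mutant 1 is assumed to vary like the controls. The number of genes lower by at least 1 with separate groups ranged from 26 to 60 over these, against 34, and genes higher by at least 1 with separate groups from 1 to 4, against 1; no gene was higher by at least 1 after further quantile normalization or under the stricter filter. With the replicate number as a block, 113 genes were lower and 3 higher, and 95 of the called genes remained; the deviations of same-numbered arrays correlated at 0.26 over genes, and nothing in the labels says that the numbers pair embryos. Of the 10 lists called lower and 3 called higher in camera, 0 and 0 passed with an estimated correlation (3 lists at an unadjusted p under 0.05, lowest adjusted p 0.379), and 0 and 0 in fry (9 lists at an unadjusted p under 0.05, lowest adjusted p 0.0506). Both tests, like the fit of genes, come from 4 arrays with 2 residual degrees of freedom. Map2k1 ranged from -0.30 to -0.07 and Map2k2 from 0.03 to 0.13 with an array left out, without passing. The cause of each other change was not tested. For the called genes that the naming rule took, 225 of 272 results under other settings of the fit of named genes and 78 of 124 with an array left out stayed past the threshold, and none reversed (every feature tested, where none passed, is not in these numbers); signal over background could not be judged from these values.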

Other observations

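Of the 141 genes that fell, 40 stand on a list fixed in advance. The genes named in this paragraph stand on none and were picked from those that fell after their values were seen, so they stand for no group of genes. They include Cybrd1 (-1.38), a ferric reductase, Has2 (-1.16), a hyaluronan synthase, Hepacam (-1.16), a cell adhesion protein, Dct (-1.06), a melanin synthesis enzyme whose mutant mean (6.07) lies under the level of the filter on dim genes, and Rlbp1 (-0.87), a retinoid-binding protein. Pbk (-0.96), a mitotic kinase, Nuf2 (-0.91), a kinetochore protein, and Foxm1 (-0.60), a transcription factor, are among them. So are the integrin subunits Itgav (-0.72) and Itgb5 (-0.71), the sterol carrier Scp2 (-0.62), the pyruvate carboxylase Pcx (-0.62) and Mt3 (-0.65), a brain metallothionein. Features of a gene disagreed for the RNA-binding protein gene Qk (-0.71; its 2 dimmer features differed by -0.03 and -0.04) and for Gstm3 (-0.61; its dimmer feature 0.09).

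Tests against vascular tissue and blood, of cell number, of sex, of the hippocampal list and of the ERK list in mutant 1 were chosen after the values they use had been seen. The microglia and macrophage markers, none of which stands on another list, had a median difference of -0.27, with -0.33 in mutant 1 and -0.19 in mutant 2. Less vascular and meningeal tissue in the mutants is argued against by the median of the 41 pooled markers of those tissues, 0.0182 on the log2 scale. They differed from the microglia markers (permutation of genes on the difference of means, two-sided p = 6.0e-05). In this permutation and the next, genes are not independent replicates, so p measures the spread between genes and not between dissections. Less blood stays open: all 5 erythroid markers had a lower mean, with a median of -0.0845, and were not told apart from the microglia markers (exact permutation, two-sided p = 0.108). For scatter of unrelated genes of this brightness, the list was set against random lists. The median lay at the 0.01 percentile of 10000 random lists of equally bright genes, 95% of which lay between -0.10 and 0.08. This repeats camera's comparison with other genes on the same values and adds only the match in brightness, so it is no independent support. Random lists do not hold markers of 1 cell type, so a joint movement of such markers between samples was not tested by them. The list did not pass in camera with an estimated correlation (adjusted p = 0.38) or in fry (adjusted p = 0.0506). Fewer microglia, or less of these transcripts per cell, may each account for it as a hypothesis and cannot be separated in bulk tissue.

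ERK feedback and target genes were lower as a list, with a lower mean for 19 of 22. Immediate early genes showed no shift, with a lower mean for 8 of 15. The ERK shift did not pass in camera with an estimated correlation (adjusted p = 0.44). The immediate early genes are dim, so a fall could be hidden. The 4 ERK genes no brighter than their median had a median of -0.26 and differed from them (exact permutation of genes on the means, two-sided p = 0.019). This rests on 4 genes, Etv4 (-0.72), Shc4 (-0.32), Ier3 (-0.20) and Epha2 (0.07), which are not independent replicates. Equal values need not mean equal signal over background, for which no detection limit was at hand. A hidden fall is therefore not excluded. Fewer radial glia and astrocytes in the mutants stay a candidate explanation for the fall of the ERK genes. The ERK median lay 0.098 above that of the 45 radial glia and astrocyte genes. By the means the gap was wider, with -0.39 for the ERK list, -0.70 for the astrocyte list and -0.69 for the radial glia list. The permutation on the means gave a two-sided p of 0.090, in which genes are not independent replicates. Lower transcription per cell stays open too, as untested.

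Mutant 1 lay further from the controls than mutant 2, with list medians of -0.41 against -0.04 for hippocampal, -0.65 against -0.30 for astrocyte, -0.28 against 0.05 for Cajal-Retzius and -0.43 against -0.15 for Notch genes. Not all lists followed. Medians in mutants 1 and 2 were -0.35 and -0.36 for oligodendrocyte precursor, -0.04 and -0.13 for BMP, and -0.01 and 0.18 for mural genes. Of genes chosen after their values were seen, Gja1, a gap junction gene, was at 8.29 in mutant 1 and 9.30 in mutant 2, and Slc1a2, a glutamate transporter, at 7.66 and 8.57, against 9.58 and 8.87 in controls. Embryo sex was not settled: the male minus female differences of mutants and controls correlated at -0.26 over genes, but this is the correlation of same-numbered arrays (0.26) with its sign turned, and an effect shared by those arrays would hide one of sex. Less hippocampal tissue in the mutant 1 dissection stays open too. Over the hippocampal genes the median of mutant 1 minus mutant 2 was -0.24 (0.01 percentile of random lists), a test that restates the gap that prompted it and sets 1 array against 1; intermediate progenitor (-0.24) and Cajal-Retzius genes (-0.22) lay close to it. A stronger fall of ERK pathway genes in mutant 1 cannot be told apart from scatter, with a median of -0.07 at the 18.8 percentile.

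Ttr, the transthyretin gene of the choroid plexus, also chosen after its values were seen, was at 9.15 on the control 2 array and between 6.50 and 7.17 on the other arrays.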
